A study of Rattus norvegicus with 9 samples.

How the data were processed

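The 9 arrays measured messenger RNA in hepatic progenitor cells of the SD strain of rat, with 3 arrays of control cells, 3 of TGF-β1 cells and 3 of cells given TGF-β1 and then EGF and SCF. Per the labels, RNA was extracted with TRIzol and a column kit, labelled with biotin by the GeneChip WT PLUS method and hybridised to Affymetrix arrays. The processing notes of the labels name Affymetrix Expression Console, RMA and Partek 6.6 without their order. The deposited values are log2 intensities on the RMA scale, as the authors processed them. Whether 1 RMA run covered the 9 arrays, and the annotation build, are not given in the sources used here.

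The value table held 45664 probe sets without missing values. Probe sets were named from the array annotation, through Entrez ID for 17955, the current symbol for 839, a synonym for 74 and the symbol of the array for 10. In all, 18878 had 1 gene symbol, 354 had several and 26432 were not named here. The probe set with the highest mean over the 9 arrays stood for each of 18041 genes, of which 771 had more than 1. Probe sets without a single symbol were left out of the tests of genes, and positions in the genome were not used here. Some values were identical between arrays of a group, with all 3 equal in at least 1 group for 2896 genes (16.1%). Signal over background, not depth, sets what an array can measure, and the number of arrays limits the precision.

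Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend or robust settings). All 9 arrays shared 1 estimate of the spread of each gene, with 6 residual and 2.27 prior degrees of freedom. Moderated 2-sided tests were adjusted by Benjamini-Hochberg over all genes within each of 3 comparisons, and an adjusted p under 0.05 was called. A permutation of 3 arrays against 3 cannot give a p below 0.1. A moderated F test compared the 3 groups. Genes called with a fold of at least 2 after TGF-β1 were followed after EGF: a gene was called back when it changed in the opposite direction, and the remaining fraction was its change against control after EGF divided by that after TGF-β1.

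The comparisons, tests, 34 gene lists, the rule for named genes and the alternatives, apart from 1 named as added, were fixed before the data were examined. Lists with at least 3 measured genes were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over the lists. Camera tests a list against the other genes, and fry tests it against no change. Named genes were a panel of 20, of which 18 were measured, and the 8 largest rises and 8 largest falls after TGF-β1 among called genes whose arrays did not overlap. They also included 6 and 6 in the other comparisons, the 2 largest rises and 2 largest falls of each list, and 5 of each class of genes that went back, did not go back or differed only after EGF. Uncharacterised names were skipped.

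Alternatives were cyclic loess, centring on array medians, quantile normalization of named probe sets, a filter at the median (5.83, 12004 genes) or at the 75th percentile in 1 group (7.24, 6656 genes), the mean of the probe sets of a gene, trend and robust settings, array weights, a block for the replicate number, the 6 compared arrays alone, an adjusted p of 0.01, a test against a fold of 2, no fold minimum, and each array left out in turn. An alternative without genes with 3 identical values in a group was chosen after seeing the data. Other splits of the arrays into groups were counted, with 100 splits of the 9 arrays and 10 for each pair of groups. The procedure was tested on simulated data made from the spread of these arrays. There 78% to 88% of genes with a fold of 1.25 were recovered, and 100% at a fold of 2, with false shares of 4.55% to 5.94%. A list of 19 genes shifted by 0.3 was found in each comparison, with 0 other lists called by camera. The simulated genes were drawn independently of each other, so this count does not show how camera fares with correlated genes.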

Results

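Messenger RNA was measured on 9 Affymetrix arrays in cultured hepatic progenitor cells of the rat (SD strain), liver cells that can give rise to hepatocytes and bile duct cells. The control cells (3 arrays) grew in medium with 10% FBS, 1 ng/mL EGF and 0.5 ng/mL SCF. The TGF-β1 cells (3 arrays) were kept for 16 days in 1 ng/mL TGF-β1, a growth factor used to drive the epithelial-mesenchymal transition, in which epithelial cells lose junctions and take up features of fibroblasts; the labels name no EGF or SCF in that medium, so the comparison with controls does not separate TGF-β1 from a lack of EGF and SCF. The EGF cells (3 arrays) had the same 16 days of TGF-β1 and then 7 days in medium with 1 ng/mL EGF and 0.5 ng/mL SCF, meant to bring about the reverse, mesenchymal-epithelial transition. The labels do not say whether the 3 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. Array medians lay between 5.73 and 5.90 on the log2 scale over 45664 probe sets, and the number of arrays limits the precision. Correlations over all probe sets ran from 0.996 to 0.998 within groups and from 0.981 to 0.993 between groups. Of 18041 genes with a probe set of their own, 8227 (45.6%) differed among the 3 groups by the moderated F test. Log2 changes are given ± the moderated standard error, with n = 3 arrays in each group.

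**Figure D1:**
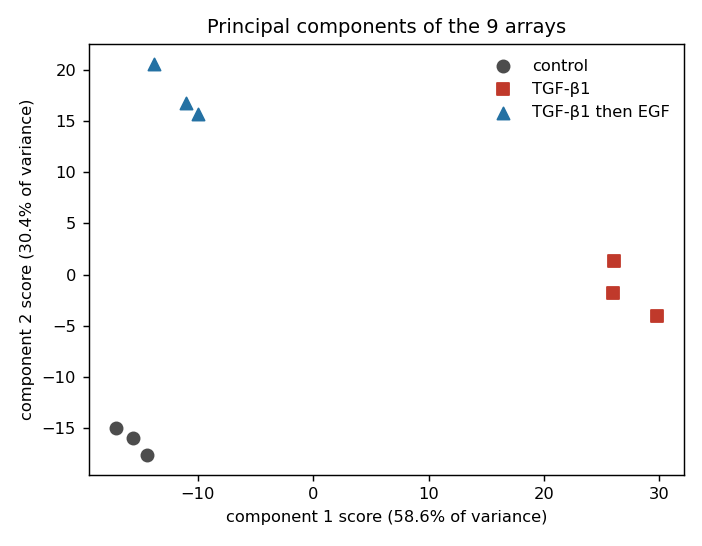
Scores of the 9 arrays on the first 2 principal components of the gene values (axes: component scores, with their shares of variance; each point is 1 array, with shape and colour for its group). Component 1 (58.6%) parts the TGF-β1 cells, with scores of 26.0 to 29.8, from both other groups, at -17.1 to -9.93, and component 2 (30.4%) parts the EGF cells from the controls.

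The comparison of TGF-β1 cells with controls asks which transcripts change in the induced transition. The contractile and collagen lists were called higher, and the mitotic, detoxification and cholesterol synthesis lists lower, by camera with a preset correlation. With an estimated correlation these 5 calls ended (adjusted p from 0.0701 to 0.346), and members of the collagen and detoxification lists went both ways. Tnfsf18, a ligand of the tumour necrosis factor family, rose 39.2-fold (log2 change 5.29 ± 0.084, adjusted p = 4.57e-09), and Akap5, a scaffold that anchors protein kinase A, rose by 4.23 ± 0.036. Tagln, an actin-binding protein of smooth muscle, rose by 4.09 ± 0.12, and Acta2, smooth muscle actin, rose 10.2-fold (3.35 ± 0.058). Aldh3a1, an aldehyde dehydrogenase, was 20.8-fold lower (-4.38 ± 0.049, adjusted p = 1.14e-09), followed by the alcohol dehydrogenase Adh1c (-4.06 ± 0.074) and the metallothionein Mt1m (-3.93 ± 0.081).

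In all, 5677 genes changed (31.5%), 2879 of them upward and 2798 downward, with a median size of 0.306 on the log2 scale. At a fold of at least 2, 182 rose and 191 fell. The groups did not overlap in 41.5% of genes, against 10% by chance for 3 arrays against 3. The other largest rises were those of Nkain4 (3.73 ± 0.062), the matrix proteoglycan Ogn (3.55 ± 0.068), Duoxa2, a maturation factor of dual oxidase (3.45 ± 0.13), and the monocyte chemokines Ccl2 (3.44 ± 0.070) and Ccl7 (3.37 ± 0.056). The other largest falls were those of the aminopeptidase Enpep (-3.47 ± 0.098), the fatty acid binding protein Fabp4 (-3.09 ± 0.041), the protease inhibitor Serpine2 (-2.98 ± 0.090), the matrix protein Efemp1 (-2.90 ± 0.061) and the receptor phosphatase Ptprz1 (-2.69 ± 0.084).

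Among epithelial panel genes, Cdh1 (E-cadherin) fell from 6.47 ± 0.071 to 5.66 ± 0.15 (mean ± SD of log2 values, n = 3, change -0.81 ± 0.076, adjusted p = 6.4e-05). Low signal near the array medians may limit its changes. Krt8 (-1.39 ± 0.045) and Tjp1 (-0.29 ± 0.060) fell. Krt18 (-0.011 ± 0.056, adjusted p = 0.911), Krt19 (0.039 ± 0.034, adjusted p = 0.434) and Ocln (0.058 ± 0.039, adjusted p = 0.308) were not called. Of the mesenchymal panel genes, Vim (vimentin) stood at 12.85 ± 0.045 in control cells and fell (-0.48 ± 0.041), while Col1a1, at 13.01 ± 0.031 in control cells, had a change of 0.0033 ± 0.027 (adjusted p = 0.948) and Cdh2 one of -0.069 ± 0.057 (adjusted p = 0.404). Fn1 (fibronectin) changed by 0.098 ± 0.025 (adjusted p = 0.0176). This call ended without control array 2 (0.089) or 3 (0.092), with median centring (0.074) or a replicate block and without genes with identical values. Quantile normalization gave -0.083 (adjusted p over all alternatives 0.0108 to 0.255). Of the transcription factors that repress Cdh1, Snai2 fell (-1.16 ± 0.11), and Snai1 (0.14 ± 0.092, adjusted p = 0.314), Zeb1 (0.13 ± 0.10, adjusted p = 0.39) and Twist1 (-0.013 ± 0.039, adjusted p = 0.831) were not called. Zeb2 (-0.16 ± 0.073, adjusted p = 0.145) was called lower without TGF-β1 array 3 (-0.25), and Tgfb1 (-0.13 ± 0.067, adjusted p = 0.186) without TGF-β1 array 2 (-0.20). Egfr, the receptor of EGF, rose by 0.72 ± 0.062.

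**Figure D2:**
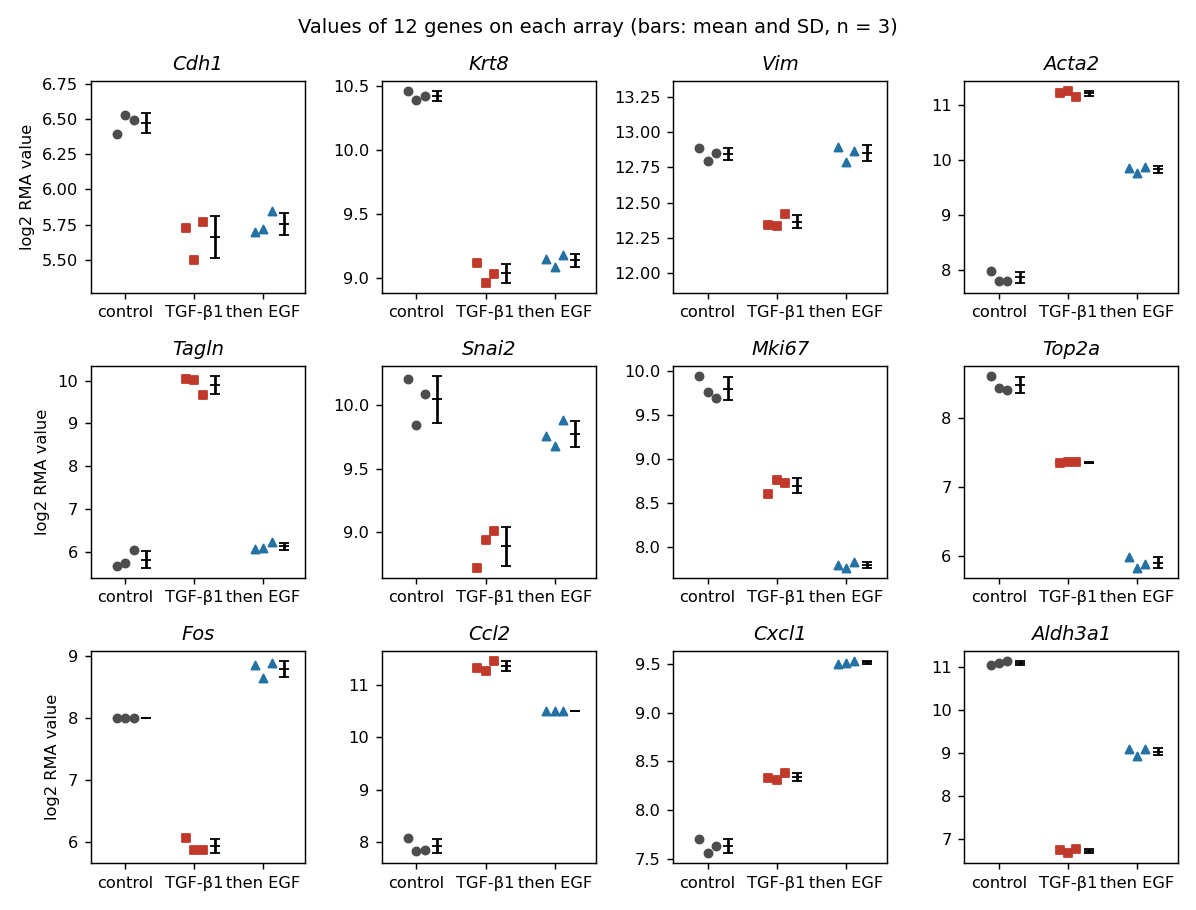
Log2 RMA values of 12 genes on each array (vertical axes, which do not start at 0; 3 arrays per group on the horizontal axis, with black bars for the mean and SD). Tagln rose with TGF-β1 and fell back after EGF, Mki67 and Top2a fell at both steps, and Cdh1 fell from 6.47 to 5.66 with TGF-β1 and stood at 5.75 after EGF, a change after EGF called only under 3 other scalings.

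Of the 34 gene lists, 5 were called higher and 9 lower. Each of these calls held under the 3 other scalings and with any 1 array left out, but 4 ended under a filter on signal (at the median or the 75th percentile of probe sets) and all 14 with an estimated correlation. In the contractile list 17 rose and 0 fell of 25 measured, 18 and 1 adjusted over the list alone (camera adjusted p = 3.4e-07, adjusted p = 0.0701 with an estimated correlation). The largest changes were those of Tagln and Acta2. Among fibrillar collagens and matrix assembly genes 21 rose and 7 fell of 35 measured, 22 and 7 adjusted over the list alone (camera adjusted p = 0.000417, adjusted p = 0.34 with an estimated correlation). The rises included Fbln2 (2.51 ± 0.045) and the collagen-modifying enzyme Plod2 (1.91 ± 0.065), while the collagen VI chains Col6a1 (-1.98 ± 0.041) and Col6a2 (-1.77 ± 0.026) fell. Among targets of the transcriptional co-activator YAP 13 rose and 1 fell of 18 measured, 13 and 1 adjusted over the list alone (camera adjusted p = 1.45e-06, adjusted p = 0.0701 with an estimated correlation). The rises included Ankrd1 (3.07 ± 0.088) and Ccn2 (1.64 ± 0.041), and the falls Myof (-0.35 ± 0.037). For WNT pathway genes 15 rose and 2 fell of 31 measured, 17 and 2 adjusted over the list alone (camera adjusted p = 0.000103, adjusted p = 0.198 with an estimated correlation). Axin2 (2.24 ± 0.056) and Nkd2 (2.19 ± 0.052), both feedback inhibitors of WNT signalling, rose, and Tcf7l2 (-1.48 ± 0.070) and Dkk3 (-0.33 ± 0.046) fell. Of genes known to be induced by TGF-β, 10 rose and 4 fell of 22 measured, 11 and 4 adjusted over the list alone (camera adjusted p = 0.00546, adjusted p = 0.208 with an estimated correlation). The rises included Pmepa1 (0.92 ± 0.033), and the falls Hmga2 (-0.58 ± 0.052) and Ski (-0.29 ± 0.048).

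Every measured mitotic gene fell: 0 rose and 30 fell of 30 measured, 0 and 30 adjusted over the list alone (camera adjusted p = 2.93e-24, adjusted p = 0.0701 with an estimated correlation). The median was -0.92, with the largest falls in the kinesin Kif11 (-1.38 ± 0.077) and the kinetochore protein Cenpf (-1.32 ± 0.16). DNA replication genes gave 1 rise and 17 falls among 29 measured, 1 and 17 adjusted over the list alone (camera adjusted p = 1.45e-06, adjusted p = 0.0701 with an estimated correlation). The falls included Pola1 (-0.87 ± 0.079) and Prim1 (-0.74 ± 0.057), and the rises cyclin E1, Ccne1 (0.50 ± 0.054). Cholesterol synthesis genes gave 0 rises and 12 falls among 19 measured, 2 and 12 adjusted over the list alone (camera adjusted p = 9.19e-06, adjusted p = 0.0701 with an estimated correlation). The largest changes were those of Hsd17b7 (-1.24 ± 0.078) and Insig1 (-0.88 ± 0.034). In the list of NRF2 targets and xenobiotic enzymes 5 rose and 11 fell of 23 measured, 5 and 11 adjusted over the list alone (camera adjusted p = 0.00546, adjusted p = 0.346 with an estimated correlation). The falls included Aldh3a1 and the cystine transporter Slc7a11 (-2.28 ± 0.087), and the rises Cyp1b1 (0.99 ± 0.039) and Hmox1 (0.50 ± 0.033). The ID family, inhibitors of basic helix-loop-helix factors, gave 0 rises and 3 falls among 4 measured, 0 and 3 adjusted over the list alone (camera adjusted p = 0.012, adjusted p = 0.149 with an estimated correlation). Changes were largest for Id2 (-2.66 ± 0.12) and Id3 (-0.57 ± 0.079). In the list of ERK feedback and immediate-early genes 6 rose and 10 fell of 24 measured, 7 and 11 adjusted over the list alone (camera adjusted p = 0.0358, adjusted p = 0.346 with an estimated correlation). Fos (-2.08 ± 0.072) and Egr1 (-1.97 ± 0.043) fell, and Ier3 (0.62 ± 0.058) and cyclin D1, Ccnd1 (0.55 ± 0.030), rose. Notch pathway genes gave 0 rises and 8 falls among 20 measured, 0 and 8 adjusted over the list alone (camera adjusted p = 0.00738, adjusted p = 0.395 with an estimated correlation). By size the first were Hey2 (-1.53 ± 0.087) and Hes1 (-1.42 ± 0.029). Interferon response genes gave 0 rises and 8 falls among 24 measured, 0 and 8 adjusted over the list alone (camera adjusted p = 0.0242, adjusted p = 0.247 with an estimated correlation). By size the first were Ifi44 (-0.57 ± 0.068) and Usp18 (-0.53 ± 0.046). The NRF2 list lost its call under the 75th percentile filter (adjusted p = 0.0946), range 0.00368 to 0.346 over camera alternatives. The ERK list lost its call under the median filter (adjusted p = 0.148), the 75th percentile filter (0.198) and removal of identical values (0.446), range 0.0246 to 0.446 over camera alternatives. The Notch list lost its call under removal of identical values (adjusted p = 0.0696), range 0.00253 to 0.395 over camera alternatives. The interferon list lost its call under the 75th percentile filter (adjusted p = 0.401) and removal of identical values (0.0627), range 0.0128 to 0.401 over camera alternatives. Removal of genes with 3 identical values in a group was chosen after seeing the data.

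**Figure D3:**
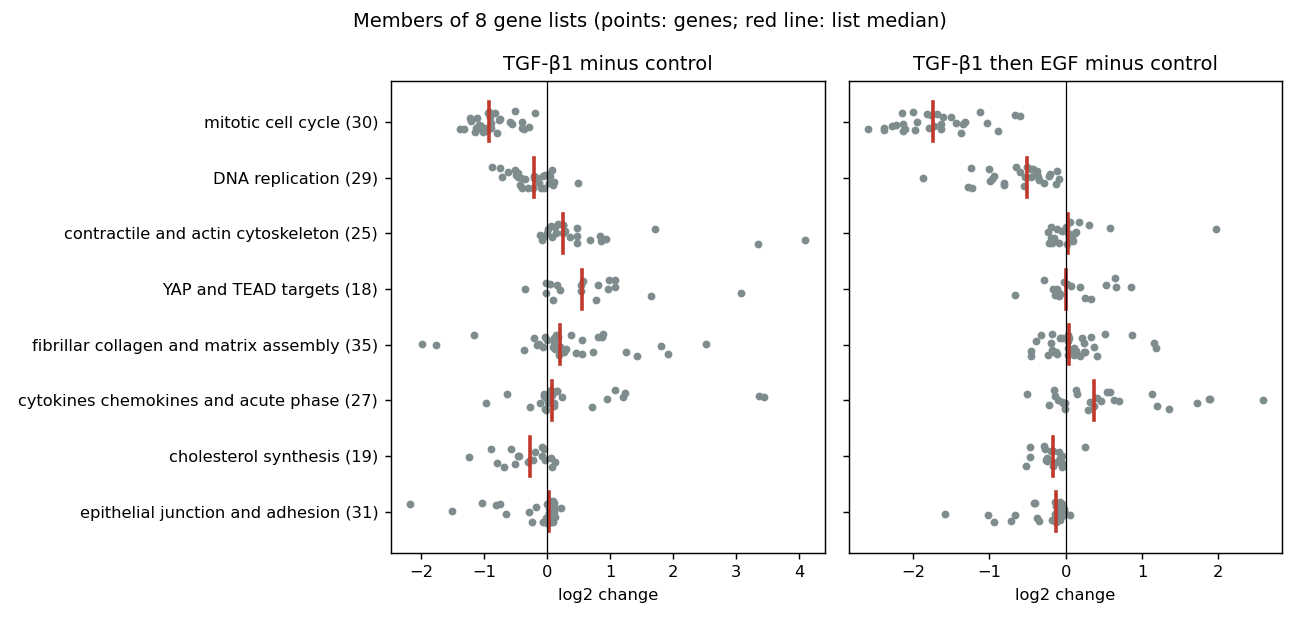
Log2 changes of the members of 8 gene lists (horizontal axes; grey points are genes, red lines the list medians, with the number of measured genes after each name) in TGF-β1 cells and in EGF cells, each minus control. The mitotic list has medians of -0.92 and -1.74, and the contractile list 0.26 and 0.031.

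Lists of epithelial and mesenchymal identity were not called with TGF-β1 in the deposited values of all 9 arrays and all genes, but junction genes were called lower and mesenchymal markers higher among genes with signal above either filter. With an estimated correlation their adjusted p over all genes was 0.555 and 0.466. For epithelial junction genes 2 rose and 9 fell of 31, 2 and 9 adjusted over the list alone (camera adjusted p = 0.0616). Their median was 0.033 but their mean -0.20, in the direction of the test, and with the filters at the median and the 75th percentile the median was -0.039 and -0.64. The desmosomal cadherin Dsg2 (-2.16 ± 0.049) and periplakin, Ppl (-1.51 ± 0.028), fell. The junction genes were called lower on leaving out control array 1 (adjusted p = 0.0413), control array 2 (0.0481) and TGF-β1 array 1 (0.0259) and under the median filter (0.0257) and the 75th percentile filter (0.0239), range 0.0239 to 0.555 over camera alternatives, the highest with an estimated correlation. For mesenchymal markers 10 rose and 4 fell of 21, 10 and 4 adjusted over the list alone (camera adjusted p = 0.0524): periostin, Postn (2.85 ± 0.048), and tenascin C, Tnc (2.43 ± 0.035), rose and S100a4 (-1.09 ± 0.054) fell with Vim. Their median was 0.051, and 0.16 and 0.18 with those filters. The mesenchymal markers were called higher on leaving out control array 1 (adjusted p = 0.0413), control array 2 (0.0481), TGF-β1 array 1 (0.0293) and TGF-β1 array 3 (0.0295) and under cyclic loess (0.0178), median centring (0.0398), the median filter (0.0185) and the 75th percentile filter (0.0149), range 0.0149 to 0.466 over camera alternatives, the highest with an estimated correlation. Keratins gave 1 rise and 1 fall among 10, 1 and 1 adjusted over the list alone (camera adjusted p = 0.753), a rise of Krt7 (1.55 ± 0.046) and the fall of Krt8. Transcription factors of the transition gave 5 rises and 2 falls among 18, 5 and 2 adjusted over the list alone (camera adjusted p = 0.289). The rises included Foxc2 (1.42 ± 0.077) and Sox4 (0.53 ± 0.044), and the falls Snai2 and Twist2 (for Twist2 -0.58 ± 0.093, not called on the mean of its probe sets, -0.22). Epithelial transcription regulators gave 1 rise and 4 falls among 17, 1 and 4 adjusted over the list alone (camera adjusted p = 0.412). The median was positive (0.039) against a negative mean (-0.16) and test. Cdx2 (-1.13 ± 0.038) and Tfap2a (-0.90 ± 0.058) fell and Klf5 (0.33 ± 0.058) rose. Basement membrane genes gave 11 rises and 4 falls among 21, 11 and 5 adjusted over the list alone (camera adjusted p = 0.0524). The rises included Nid1 (1.13 ± 0.054) and Col4a1 (0.85 ± 0.031). The basement membrane genes were called higher on leaving out control array 1 (adjusted p = 0.05), control array 2 (0.0481) and TGF-β1 array 3 (0.0396) and under cyclic loess (0.0406) and removal of identical values (0.0369), range 0.0369 to 0.208 over camera alternatives, the highest with an estimated correlation. TGF-β ligands, receptors and SMADs gave 14 rises and 5 falls among 28, 15 and 5 adjusted over the list alone (camera adjusted p = 0.0616). The rises included Lrrc32 (2.04 ± 0.054) and Tgfb2 (1.08 ± 0.052), and the falls Tgfbr3 (-1.56 ± 0.052). The TGF-β ligand list was called higher on leaving out control array 1 (adjusted p = 0.0419) and control array 2 (0.0481) and under cyclic loess (0.0178) and quantile normalization (0.0333), range 0.0178 to 0.466 over camera alternatives, the highest with an estimated correlation. Cytokines and chemokines gave 8 rises and 4 falls among 27, 9 and 4 adjusted over the list alone (camera adjusted p = 0.0616). Ccl2 and Ccl7 were higher and the NF-κB inhibitors Nfkbia (-0.96 ± 0.066) and Tnfaip3 (-0.64 ± 0.069) lower. The cytokine list was called higher on leaving out control array 2 (adjusted p = 0.0481) and under median centring (0.0331), range 0.0331 to 0.346 over camera alternatives, the highest with an estimated correlation. CDK inhibitors and senescence genes gave 5 rises and 4 falls among 17, 5 and 4 adjusted over the list alone (camera adjusted p = 0.864). Their median (-0.042) lay below 0 and their mean (0.16) and test above it. Igfbp7 (1.86 ± 0.048) rose and lamin B1, Lmnb1 (-0.75 ± 0.044), fell.

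Among markers of other liver cell types, stellate cell genes gave 1 rise and 2 falls among 12, 1 and 2 adjusted over the list alone (camera adjusted p = 0.824). Their median was 0.045 against a mean of -0.096 and a downward test, and Des fell (-1.59 ± 0.042). Endothelial genes gave 3 rises and 0 falls among 15, 0 and 0 adjusted over the list alone (camera adjusted p = 0.196). Macrophage and leukocyte genes gave 1 rise and 2 falls among 16, 1 and 2 adjusted over the list alone (camera adjusted p = 0.864). The macrophage list had a negative mean (-0.073) against a positive median (0.046) and test, and Cd14 (-1.36 ± 0.043) and Cd68 (-1.27 ± 0.10) fell. Y-linked transcripts, counted as a check for mixed samples, gave 0 rises and 3 falls among 4 measured, 0 and 4 adjusted over the list alone (camera adjusted p = 0.036, adjusted p = 0.395 with an estimated correlation). Y-linked transcripts lost their call under the median filter (adjusted p = 0.0815) and the 75th percentile filter (0.156), range 0.0291 to 0.395 over camera alternatives. In control cells 7 of 12 stellate markers, 2 of 15 endothelial markers and 5 of 16 macrophage markers lay above the median of all probe sets.

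The comparison of EGF cells with TGF-β1 cells asks what EGF and SCF without TGF-β1 undo. The contractile, basement membrane, YAP target and mitotic lists were called lower, and the ID and interferon lists higher, by camera with a preset correlation. With an estimated correlation these 6 calls ended (adjusted p = 0.139 for each), and members of each list but the mitotic went both ways. Tnfsf18 fell (-4.66 ± 0.084, adjusted p = 1.48e-08), as did Tagln (-3.78 ± 0.12) and Acta2 (-1.38 ± 0.058). Mt1m rose by 3.36 ± 0.081 (adjusted p = 5.91e-08), Enpep by 3.06 ± 0.098, the joint lubricant proteoglycan Prg4 by 3.04 ± 0.11 and osteopontin, Spp1, by 2.65 ± 0.048. Fos (2.87 ± 0.072) and Egr1 (2.61 ± 0.043), transcription factors induced within minutes of growth factor signals, rose as well.

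A total of 8617 genes changed (47.8%), 3330 upward and 5287 downward, with a median size of 0.26. The split depended on the scaling: 38.6% of the calls were upward in the deposited values, against 53.1% with cyclic loess, 68.7% with median centring and 52.5% with quantile normalization. At a fold of at least 2, 140 rose and 141 fell, 49.8% of them upward, and 48.4%, 60.8% and 48.8% were upward under those scalings. The groups did not overlap in 53.3% of genes, against 10% by chance. Other large falls were those of Duoxa2 (-3.71 ± 0.13), the interleukin 33 receptor Il1rl1 (-3.49 ± 0.047), Akap5 (-3.40 ± 0.036) and Prl8a9, of the prolactin family (-3.30 ± 0.063).

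In the fixed panel, Vim rose by 0.48 ± 0.041, Snai2 by 0.89 ± 0.11, Zeb2 by 0.61 ± 0.073, Zeb1 by 0.40 ± 0.10 and Tjp1 by 0.25 ± 0.060, and the N-cadherin gene Cdh2 (-0.66 ± 0.057) and Egfr (-0.36 ± 0.062) fell. Cdh1 had a change of 0.092 ± 0.076 (adjusted p = 0.322) but was called higher with cyclic loess (0.20), median centring (0.19) and quantile normalization (0.21). Krt19 had a change of 0.057 ± 0.034 (adjusted p = 0.186), called under the same 3 scalings (0.14, 0.15 and 0.11), and Krt8 one of 0.10 ± 0.045 (adjusted p = 0.0914), called with median centring (0.20), with array weights (0.14) and without TGF-β1 array 1 (0.14). Krt18 (-0.093 ± 0.056), Fn1 (-0.057 ± 0.025) and Twist1 (-0.012 ± 0.039) were not called. Further changes crossed the threshold under single settings: Ocln (-0.11 ± 0.039) without EGF array 2 (-0.13), and Col1a1 (0.023 ± 0.027) and Snai1 (0.18 ± 0.092) with median centring (0.12 and 0.28). Tgfb1 had a change of 0.22 ± 0.067 (adjusted p = 0.0262), a call that ended with cyclic loess (0.14) and without TGF-β1 array 1 (0.16), TGF-β1 array 3 (0.22), EGF array 1 (0.20) or EGF array 3 (0.20), and with a replicate block or the 6 compared arrays, with adjusted p over all alternatives of 0.00444 to 0.096.

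Of the 34 lists, 7 were called higher and 10 lower. Mitotic genes fell further: 0 rose and 30 fell of 30 measured, 0 and 30 adjusted over the list alone (camera adjusted p = 6.09e-15, adjusted p = 0.139 with an estimated correlation). The median was -0.79, and the largest falls were those of topoisomerase Top2a (-1.46 ± 0.060) and Kif20a (-1.34 ± 0.048). In the DNA replication list 0 rose and 24 fell of 29 measured, 1 and 25 adjusted over the list alone (camera adjusted p = 4.48e-07, adjusted p = 0.139 with an estimated correlation). Changes were largest for Rrm2, a subunit of ribonucleotide reductase (-1.41 ± 0.045), and the helicase subunit Mcm3 (-0.93 ± 0.037). Contractile genes gave 2 rises and 21 falls among 25 measured, 2 and 22 adjusted over the list alone (camera adjusted p = 1.7e-06, adjusted p = 0.139 with an estimated correlation). YAP targets gave 1 rise and 15 falls among 18 measured, 1 and 15 adjusted over the list alone (camera adjusted p = 4.65e-05, adjusted p = 0.139 with an estimated correlation). The falls included Ankrd1 (-2.88 ± 0.088) and Nuak2 (-1.09 ± 0.065), and the rises Gadd45a (0.49 ± 0.035). Basement membrane genes gave 2 rises and 11 falls among 21 measured, 2 and 13 adjusted over the list alone (camera adjusted p = 0.0292, adjusted p = 0.139 with an estimated correlation). The falls included Nid1 (-1.17 ± 0.054), and the rises Lama4 (0.61 ± 0.043). The basement membrane genes lost their call under the median filter (adjusted p = 0.0536) and the 75th percentile filter (0.108), range 0.00519 to 0.139 over camera alternatives. The ID family gave 3 rises and 1 fall among 4 measured, 3 and 1 adjusted over the list alone (camera adjusted p = 0.0203, adjusted p = 0.139 with an estimated correlation). The rises included Id2 (1.81 ± 0.12) and Id3 (0.80 ± 0.079). Interferon response genes gave 10 rises and 2 falls among 24 measured, 11 and 2 adjusted over the list alone (camera adjusted p = 0.000618, adjusted p = 0.139 with an estimated correlation). By size the first were Mx1 (1.22 ± 0.041) and Ifi44 (0.79 ± 0.068). The interferon list lost its call under the 75th percentile filter (adjusted p = 0.387), range 0.000442 to 0.387 over camera alternatives. Y-linked transcripts gave 4 rises and 0 falls among 4 measured, 4 and 0 adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.417 with an estimated correlation). The largest change was that of Uty (0.86 ± 0.075). Y-linked transcripts lost their call under the median filter (adjusted p = 0.0539) and the 75th percentile filter (0.14), range 0.00766 to 0.417 over camera alternatives. Cholesterol synthesis genes gave 8 rises and 3 falls among 19 measured, 8 and 3 adjusted over the list alone (camera adjusted p = 0.0307, adjusted p = 0.353 with an estimated correlation). The rises included Hsd17b7 (0.77 ± 0.078) and Insig1 (0.60 ± 0.034). Cholesterol synthesis genes lost their call under cyclic loess (adjusted p = 0.106), quantile normalization (0.155), the median filter (0.175), the 75th percentile filter (0.119) and removal of identical values (0.0735), range 0.0208 to 0.353 over camera alternatives.

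A further group of list calls ended when single arrays were left out. Mesenchymal markers gave 3 rises and 11 falls among 21 measured, 3 and 13 adjusted over the list alone (camera adjusted p = 0.0462, adjusted p = 0.606 with an estimated correlation). Postn (-1.41 ± 0.048) and Tnc (-1.33 ± 0.035) fell, and S100a4 (0.73 ± 0.054) and Vim rose. The mesenchymal markers lost their call on leaving out control array 2 (adjusted p = 0.0516), control array 3 (0.0569), TGF-β1 array 2 (0.109), EGF array 2 (0.0646) and EGF array 3 (0.0537) and under median centring (0.0557), quantile normalization (0.0602), the median filter (0.0542), array weights (0.0534), a replicate block (0.0736), removal of identical values (0.242) and the 6 compared arrays (0.0591), range 0.00691 to 0.606 over camera alternatives. The collagen list gave 6 rises and 20 falls among 35 measured, 6 and 21 adjusted over the list alone (camera adjusted p = 0.0462, adjusted p = 0.674 with an estimated correlation). Fbln2 (-2.97 ± 0.045) and Loxl2 (-1.30 ± 0.033) fell, and Col6a1 (1.66 ± 0.041) and Col6a3 (1.42 ± 0.030) rose. The collagen list lost its call on leaving out control array 2 (adjusted p = 0.0516), control array 3 (0.0509), TGF-β1 array 2 (0.11) and EGF array 2 (0.0792) and under array weights (0.0621), a replicate block (0.066), removal of identical values (0.108) and the 6 compared arrays (0.0591), range 7.26e-05 to 0.674 over camera alternatives. WNT pathway genes gave 4 rises and 17 falls among 31 measured, 4 and 18 adjusted over the list alone (camera adjusted p = 0.0462, adjusted p = 0.529 with an estimated correlation). The falls included Wnt7a (-1.49 ± 0.048), and the rises Tcf7l2 (2.83-fold) and Dkk3 (0.24 ± 0.046). The WNT genes lost their call on leaving out control array 2 (adjusted p = 0.0553), control array 3 (0.0536), TGF-β1 array 1 (0.0573), TGF-β1 array 3 (0.0645), EGF array 1 (0.055) and EGF array 2 (0.0628) and under the median filter (0.0542), the 75th percentile filter (0.108), array weights (0.0621), a replicate block (0.0565) and the 6 compared arrays (0.0591), range 0.0152 to 0.529 over camera alternatives. In the ERK list 11 rose and 7 fell of 24 measured, 11 and 7 adjusted over the list alone (camera adjusted p = 0.0462, adjusted p = 0.44 with an estimated correlation). The list was called higher, with Fos and Egr1 among the rises. Dusp6, an ERK phosphatase induced by ERK itself (-0.95 ± 0.029), and Ccnd1 (-0.86 ± 0.030) fell. The ERK list lost its call on leaving out control array 2 (adjusted p = 0.0516), control array 3 (0.0509) and TGF-β1 array 2 (0.0528) and under cyclic loess (0.102), median centring (0.104), quantile normalization (0.124), the median filter (0.295), the 75th percentile filter (0.478), removal of identical values (0.635) and the 6 compared arrays (0.0591), range 0.0257 to 0.635 over camera alternatives. Cytokine and chemokine genes gave 13 rises and 8 falls among 27 measured, 13 and 8 adjusted over the list alone (camera adjusted p = 0.0462, adjusted p = 0.417 with an estimated correlation). The direction was higher. Nfkbia (2.09 ± 0.066) and Ptgs2 (1.62 ± 0.055) rose, and Ccl7 (-1.49 ± 0.056) and Ccl2 (-0.85 ± 0.070) fell. The cytokine list lost its call on leaving out control array 1 (adjusted p = 0.0557), control array 2 (0.0516), control array 3 (0.0509), TGF-β1 array 2 (0.0528), TGF-β1 array 3 (0.053) and EGF array 2 (0.0664) and under cyclic loess (0.102), median centring (0.166), quantile normalization (0.0711), the median filter (0.397), the 75th percentile filter (0.995), array weights (0.0621) and the 6 compared arrays (0.0591), range 0.00883 to 0.995 over camera alternatives. Endothelial markers gave 0 rises and 8 falls among 15 measured, 0 and 11 adjusted over the list alone (camera adjusted p = 0.0462, adjusted p = 0.674 with an estimated correlation). The endothelial markers lost their call on leaving out control array 2 (adjusted p = 0.0516), control array 3 (0.0509), TGF-β1 array 1 (0.0834) and EGF array 1 (0.055) and under cyclic loess (0.247), median centring (0.0594), quantile normalization (0.372), array weights (0.0621), removal of identical values (0.0705) and the 6 compared arrays (0.0591), range 0.0213 to 0.674 over camera alternatives. Without control array 2, and likewise without control array 3, 10 lists were called in place of 17.

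The remaining lists on cell identity and signalling were not called after EGF. Epithelial junction genes gave 4 rises and 11 falls among 31, 4 and 13 adjusted over the list alone (camera adjusted p = 0.5). Ppl (1.13 ± 0.028) and desmoplakin, Dsp (0.63 ± 0.058), rose, and the desmosomal plakophilin Pkp2 (-1.16 ± 0.063) and the protease St14 (-0.40 ± 0.066) fell. For keratins 0 rose and 5 fell of 10, 0 and 5 adjusted over the list alone (camera adjusted p = 0.0737). The falls included Krt14 (-2.33 ± 0.069) and Krt7 (-2.22 ± 0.046). The keratins were called lower under median centring (adjusted p = 0.0447) and the 75th percentile filter (0.0376), range 0.0376 to 0.44 over camera alternatives, the highest with an estimated correlation. Epithelial transcription regulators gave 5 rises and 4 falls among 17, 5 and 4 adjusted over the list alone (camera adjusted p = 0.306). A negative median (-0.043), which turned positive with median centring, stood against a positive mean (0.12) and test. Trps1 (1.14 ± 0.067) and Klf4 (0.81 ± 0.062) rose. Transcription factors of the transition gave 6 rises and 6 falls among 18, 6 and 7 adjusted over the list alone (camera adjusted p = 0.353). The rises included Twist2 (0.73 ± 0.093, not called on the mean of its probe sets, 0.24), and the falls Foxc2 (-0.71 ± 0.077). TGF-β ligands, receptors and SMADs gave 10 rises and 9 falls among 28, 10 and 9 adjusted over the list alone (camera adjusted p = 0.536). The median (-0.039) and mean (-0.026) were negative and the test upward, and the test turned downward with cyclic loess and quantile normalization. Genes induced by TGF-β gave 9 rises and 8 falls among 22, 9 and 9 adjusted over the list alone (camera adjusted p = 0.5). Here a negative mean (-0.058) stood against a positive median (0.055) and test, and the test turned downward with the same scalings. Among them Ccn2 (-0.99 ± 0.041) and Pmepa1 (-0.97 ± 0.033) fell and Tgfbi (0.81 ± 0.061) rose. Notch pathway genes gave 7 rises and 7 falls among 20, 7 and 9 adjusted over the list alone (camera adjusted p = 0.249). Their median was -0.11 but their mean 0.24, in the direction of the test, and Hes1 (2.27 ± 0.029) and Hey2 (1.54 ± 0.087) rose. CDK inhibitors and senescence genes gave 4 rises and 11 falls among 17, 4 and 13 adjusted over the list alone (camera adjusted p = 0.285). The falls included Igfbp7 (-0.91 ± 0.048), and the rises Igfbp5 (1.32 ± 0.050). The CDK inhibitor list was called lower under cyclic loess (adjusted p = 0.0483), range 0.0483 to 0.71 over camera alternatives, the highest with an estimated correlation. NRF2 targets gave 8 rises and 7 falls among 23, 8 and 7 adjusted over the list alone (camera adjusted p = 0.237). The rises included Aldh3a1 (2.31 ± 0.049) and Slc7a11 (2.04 ± 0.087), and the falls the glutathione transferase Gsta2 (-1.15 ± 0.064). Stellate cell markers gave 1 rise and 6 falls among 12, 1 and 7 adjusted over the list alone (camera adjusted p = 0.334). The rises included Des (2.38-fold). Macrophage and leukocyte markers gave 2 rises and 6 falls among 16, 2 and 6 adjusted over the list alone (camera adjusted p = 0.388).

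The comparison of EGF cells with controls asks what differed after the full cycle of treatment, when both groups grew with EGF and SCF. The list of cytokines, chemokines and acute phase genes was called higher and the mitotic and DNA replication lists lower than in controls, by camera with either correlation. Genes induced by TGF-β were called higher and the junction and detoxification lists lower, calls that ended with an estimated correlation (adjusted p = 0.138, 0.325 and 0.432). Abi3bp, a matrix-binding protein, was 10.3-fold higher (3.36 ± 0.053, adjusted p = 1.73e-08), Ccl2 was higher by 2.58 ± 0.070 and Acta2 by 1.97 ± 0.058. Efemp1 was 7.31-fold lower (-2.87 ± 0.061, adjusted p = 3.8e-08), and Fabp4 (-2.74 ± 0.041) and Top2a (-2.59 ± 0.060), which untangles DNA in dividing cells, were lower too. The proliferation marker Mki67, chosen after its values were seen, differed by -2.00 ± 0.068 (adjusted p = 2.66e-07).

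In total 4070 genes differed (22.6%), 2152 higher and 1918 lower, with a median size of 0.274. Of these calls 52.9% were upward, against 58.3% with cyclic loess, 74.1% with median centring and 56.5% with quantile normalization. At a fold of at least 2, 60 were higher and 161 lower. The groups did not overlap in 41.7% of genes, against 10% by chance. The integrin-like Itgbl1 (1.98 ± 0.035) and the chemokines Cxcl1 (1.89 ± 0.040) and Ccl7 (1.88 ± 0.056) were among the largest differences upward, and the cytochrome Cyp3a9 (-2.48 ± 0.10), the water channel Aqp1 (-2.47 ± 0.041) and Gsta2 (-2.46 ± 0.064) among the largest downward. Genes that differed here without having been called with TGF-β1 numbered 1472, and of those with a fold of at least 2, 4 were higher and 4 lower; by size they were led by keratin Krt14 (-2.26 ± 0.069), ceruloplasmin, Cp (1.73 ± 0.11), Ets2 (1.32 ± 0.058), Stmn2 (-1.28 ± 0.044) and Kpna2 (-1.24 ± 0.075).

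Within the fixed panel, Cdh1 was lower than in controls at -0.71 ± 0.076 (adjusted p = 0.00023), Krt8 at -1.29 ± 0.045 and Cdh2 at -0.73 ± 0.057. Zeb1 (0.53 ± 0.10), Zeb2 (0.45 ± 0.073) and Egfr (0.36 ± 0.062) were higher. Vim (0.0039 ± 0.041, adjusted p = 0.958), Tjp1 (-0.041 ± 0.060, adjusted p = 0.635), Ocln (-0.047 ± 0.039), Krt18 (-0.10 ± 0.056) and Twist1 (-0.026 ± 0.039) were not called. Col1a1 (0.027 ± 0.027), Fn1 (0.041 ± 0.025) and Tgfb1 (0.092 ± 0.067) were called higher only with array weights (0.061, 0.050 and 0.12). Krt19 (0.097 ± 0.034, adjusted p = 0.0815) was called higher with the 3 other scalings (0.14, 0.17 and 0.13), with array weights (0.12) and without EGF array 2 (0.12). Snai2 (-0.27 ± 0.11, adjusted p = 0.112) was called lower with cyclic loess (-0.29), quantile normalization (-0.27) and without control array 2 (-0.37). Snai1 had a difference of 0.32 ± 0.092 (adjusted p = 0.0387), a call that ended without control array 1 (0.34), control array 2 (0.22), any TGF-β1 array (0.32), EGF array 1 (0.24) or EGF array 3 (0.35), and with the 6 compared arrays, with adjusted p over all alternatives of 0.00445 to 0.125.

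Here 8 of the 34 lists were called higher and 7 lower, and 3 of these calls held with an estimated correlation. In the mitotic list 0 rose and 30 fell of 30 measured, 0 and 30 adjusted over the list alone (camera adjusted p = 1.25e-36, adjusted p = 0.041 with an estimated correlation), and the median was -1.74. DNA replication genes gave 0 rises and 27 falls among 29 measured, 0 and 27 adjusted over the list alone (camera adjusted p = 8.4e-20, adjusted p = 0.0142 with an estimated correlation). The largest changes were those of Rrm2 (-1.87 ± 0.045) and Mcm5 (-1.29 ± 0.038). Cytokines, chemokines and acute phase genes gave 17 rises and 1 fall among 27 measured, 17 and 3 adjusted over the list alone (camera adjusted p = 7.36e-09, adjusted p = 0.041 with an estimated correlation). By size the first were Ccl2 and Cxcl1, while interleukin 33, Il33 (-0.50 ± 0.070), was lower. Epithelial junction genes gave 0 rises and 11 falls among 31 measured, 0 and 11 adjusted over the list alone (camera adjusted p = 3.85e-05, adjusted p = 0.325 with an estimated correlation). The largest changes were those of Dsg2 (-1.58 ± 0.049) and plakoglobin, Jup (-1.02 ± 0.025). Keratins gave 0 rises and 4 falls among 10 measured, 1 and 4 adjusted over the list alone (camera adjusted p = 0.00407, adjusted p = 0.255 with an estimated correlation). Changes were largest for Krt14 and Krt8. Genes induced by TGF-β gave 12 rises and 1 fall among 22 measured, 15 and 2 adjusted over the list alone (camera adjusted p = 0.000173, adjusted p = 0.138 with an estimated correlation). The rises included Tgfbi (1.49 ± 0.061) and Ccn2 (0.65 ± 0.041). TGF-β ligands, receptors and SMADs gave 12 rises and 4 falls among 28 measured, 12 and 4 adjusted over the list alone (camera adjusted p = 0.00407, adjusted p = 0.355 with an estimated correlation). The rises included Tgfb2 (0.86 ± 0.052) and Tgfbr1 (0.66 ± 0.070). Cholesterol synthesis genes gave 0 rises and 11 falls among 19 measured, 1 and 12 adjusted over the list alone (camera adjusted p = 0.000267, adjusted p = 0.138 with an estimated correlation). The largest change was that of Fdft1 (-0.52 ± 0.061). NRF2 targets gave 3 rises and 12 falls among 23 measured, 3 and 14 adjusted over the list alone (camera adjusted p = 0.00547, adjusted p = 0.432 with an estimated correlation). The falls included Gsta2 and Aldh3a1 (-2.07 ± 0.049), and the rises Gclc (0.36 ± 0.047). Interferon response genes gave 6 rises and 1 fall among 24 measured, 6 and 1 adjusted over the list alone (camera adjusted p = 0.0278, adjusted p = 0.355 with an estimated correlation). The rises included Mx1 (0.98 ± 0.041) and Stat2 (0.46 ± 0.062). The interferon list lost its call under the median filter (adjusted p = 0.382) and the 75th percentile filter (0.631), range 0.00419 to 0.631 over camera alternatives.

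The remaining calls depended on the scaling. Transcription factors of the transition gave 9 rises and 1 fall among 18 measured, 9 and 5 adjusted over the list alone (camera adjusted p = 0.0232, adjusted p = 0.355 with an estimated correlation). The rises included Foxc2 (0.71 ± 0.077) and Prrx2 (0.63 ± 0.049). The transition factors lost their call under cyclic loess (adjusted p = 0.0527), median centring (0.0758), quantile normalization (0.0599) and the 75th percentile filter (0.122), range 0.00708 to 0.355 over camera alternatives. The collagen list gave 15 rises and 8 falls among 35 measured, 15 and 9 adjusted over the list alone (camera adjusted p = 0.0113, adjusted p = 0.457 with an estimated correlation). The rises included Col12a1 (1.18 ± 0.034) and Thbs2 (1.16 ± 0.036). The collagen list lost its call under cyclic loess (adjusted p = 0.332), median centring (0.0918), quantile normalization (0.248), the median filter (0.13) and the 75th percentile filter (0.359), range 0.00335 to 0.457 over camera alternatives. WNT pathway genes gave 10 rises and 2 falls among 31 measured, 10 and 3 adjusted over the list alone (camera adjusted p = 0.049, adjusted p = 0.456 with an estimated correlation). Nkd2 (1.61 ± 0.052) and Axin2 (2.37-fold) were higher, and a median of -0.0078, positive under the 3 other scalings, stood against a mean of 0.13 and an upward test. The WNT genes lost their call on leaving out control array 1 (adjusted p = 0.0909), TGF-β1 array 1 (0.066), TGF-β1 array 2 (0.0747), TGF-β1 array 3 (0.0634), EGF array 2 (0.0941) and EGF array 3 (0.0662) and under cyclic loess (0.0871), median centring (0.108), quantile normalization (0.0599), the median filter (0.0873), trend and robust settings (0.0508), array weights (0.0751), a replicate block (0.054) and the 6 compared arrays (0.101), range 0.0151 to 0.456 over camera alternatives. Stellate cell markers gave 0 rises and 3 falls among 12 measured, 0 and 3 adjusted over the list alone (camera adjusted p = 0.0353, adjusted p = 0.456 with an estimated correlation). The falls included Ecm1 (-0.42 ± 0.056) and Des (-0.34 ± 0.042). The stellate markers lost their call on leaving out EGF array 1 (adjusted p = 0.0832) and under cyclic loess (0.074), quantile normalization (0.0906), the median filter (0.0537), the 75th percentile filter (0.0865) and array weights (0.0589), range 0.023 to 0.456 over camera alternatives. Contractile genes were not called, where 4 rose and 6 fell of 25, 7 and 6 adjusted over the list alone (camera adjusted p = 0.32). YAP targets gave 6 rises and 3 falls among 18, 6 and 3 adjusted over the list alone (camera adjusted p = 0.184). Their median (-0.0030) turned positive with median centring and quantile normalization, and their mean was 0.11, with an upward test. Mesenchymal markers gave 7 rises and 7 falls among 21, 7 and 8 adjusted over the list alone (camera adjusted p = 0.258). Their median (-0.038) turned positive with median centring, and their mean was 0.16, with an upward test. Postn (1.44 ± 0.048) and Pdgfrb (1.26 ± 0.043) were higher. Basement membrane genes gave 5 rises and 5 falls among 21, 5 and 6 adjusted over the list alone (camera adjusted p = 0.326), while in Notch genes 2 rose and 4 fell of 20, 2 and 4 adjusted over the list alone (camera adjusted p = 0.258). ERK genes gave 7 rises and 8 falls among 24, 7 and 8 adjusted over the list alone (camera adjusted p = 0.655), in a direction that turned with median centring and quantile normalization. CDK inhibitors gave 8 rises and 5 falls among 17, 8 and 5 adjusted over the list alone (camera adjusted p = 0.207). Epithelial transcription regulators gave 3 rises and 2 falls among 17, 4 and 2 adjusted over the list alone (camera adjusted p = 0.655). The ID family gave 1 rise and 1 fall among 4, 2 and 1 adjusted over the list alone (camera adjusted p = 0.754). Its median (0.073) and test were positive against a mean of -0.12, and the test turned with median centring. Endothelial markers gave 0 rises and 1 fall among 15, 0 and 0 adjusted over the list alone (camera adjusted p = 0.134). Macrophage markers gave 0 rises and 2 falls among 16, 0 and 2 adjusted over the list alone (camera adjusted p = 0.0528). The macrophage markers were called lower on leaving out control array 1 (adjusted p = 0.0303) and EGF array 2 (0.0111) and under the 75th percentile filter (0.045) and array weights (0.033), range 0.0111 to 0.613 over camera alternatives, the highest with an estimated correlation. Y-linked transcripts gave 1 rise and 0 falls among 4, 1 and 0 adjusted over the list alone (camera adjusted p = 0.154).

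A last comparison asks how far genes changed at least 2-fold in TGF-β1 cells went back in the EGF step, whether TGF-β1, EGF, SCF or time moved them. Of 373 such genes, 323 (86.6%) moved back significantly after EGF, and 264 (70.8%) still differed from control in the original direction. The median fraction of the log2 change that remained was 0.331 (0.326 to 0.342 on leaving out 1 array, and 0.332 to 0.336 from single EGF arrays), with quartiles over genes of 0.129 and 0.624. The genes with the largest changes that went back and no longer differed from control were Tagln (4.09 ± 0.12 with TGF-β1, 0.31 ± 0.12 after EGF, both against control), Duoxa2 (3.45 and -0.26), Prl8a9 (3.21 and -0.087), the pseudogene Zfp35-ps1 (3.13 and 0.34) and Ankrd1 (3.07 and 0.19). Those that did not go back were led by Efemp1 (-2.90 and -2.87), Abi3bp (2.61 and 3.36), Aqp1 (-2.19 and -2.47), the helicase Ddx11 (-2.05 and -1.85) and Sh2d1b (-1.82 and -1.62).

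By class, 84 genes moved back and were not different from control, 214 moved back but still differed, 25 moved past the control level, and 50 were not called back, 32 of which moved further away. Of the genes higher in TGF-β1 cells, 172 of 182 (94.5%) moved back, and of those lower, 151 of 191 (79.1%), a difference that was not tested. Their median remaining fractions were 0.294 ± 0.0186 and 0.369 ± 0.0197 (SD, n = 3 arrays), an order that turned with median centring (0.36 and 0.304). Both steps share the TGF-β1 arrays. In 20 simulations with EGF cells equal to TGF-β1 cells 0% were called back (remaining fraction 0.997). If equal to controls, 0% still differed (0.00251). Adjustment over unchanged genes calls few, so 0% is no chance rate. Over all genes, which are not independent replicates, the changes with TGF-β1 and after EGF correlated at -0.706, against -0.5 simulated with no effect, and their covariance was -0.0765 against -0.00178. Changes against control in the TGF-β1 and EGF cells correlated at 0.441, against 0.498 simulated, with a covariance of 0.0377 against 0.00177, and had the same sign in 46.4% of genes, against 66.6% simulated. Genes called higher and then lower numbered 2041, and lower and then higher 1944, where independent lists would share 844 and 516, and 137 were higher in both and 295 lower in both, against 531 and 820. In both comparisons against control, 987 genes were higher and 975 lower, where independent lists would share 343 and 297, while 398 were lower in TGF-β1 and higher in EGF cells and 238 the other way, against 334 and 306. The 3 arrays of a group cannot be split into parts of at least 2, so part of each difference from independence may come from the shared arrays.

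**Figure D4:**
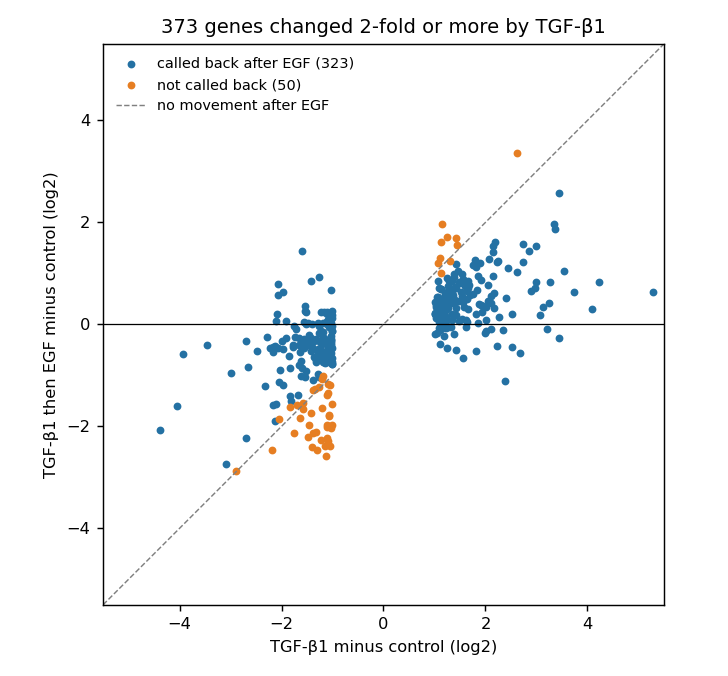
Log2 change against control after TGF-β1 (horizontal axis) and after TGF-β1 then EGF (vertical axis) of the 373 genes changed at least 2-fold in TGF-β1 cells; each point is 1 gene, coloured by whether it was called back after EGF. The 323 genes called back lie toward the horizontal axis, with 50 others on or beyond the dashed line of no movement or short of the test.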

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

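The splits of the arrays were planned, and the tests weighed for the 3 patterns were chosen only after the results were seen. Probe sets without a single gene symbol, 26786 in number, were left out of the comparisons, and those that differed from the control arrays drew attention. Of these, 69 were at least 2-fold higher and 73 lower in TGF-β1 cells than in controls, and 27 higher and 38 lower in EGF cells than in controls. The largest rise with TGF-β1 was 4.68 ± 0.14 (log2, n = 3), followed by a change of -3.71 after EGF.

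Other splits of the 9 arrays tested whether the counts come from grouping. Of 100 splits only the real one gave as many as 8227 genes differing among the 3 groups (highest other 3191). If arrays are technical repeats, chance between cultures stays open. For the 323 genes called back 1 of 100 splits gave as many, but this count decides nothing: 5 of the 99 other splits called genes with a fold of at least 2 in the first step, at most 130, so that 323 could not be reached. The highest other split gave 0 genes called back by limma, and 4 at an unadjusted p under 0.05, against 325 in the real split. For each pair of groups the 10 splits are too few for a share under 0.05. There limma called 5677, 8617 and 4070 genes in the real splits and 0 in the highest other, and with a fold of at least 2 it called 373, 281 and 221 against 0. At an unadjusted p under 0.05 limma called at most 1403, 2134 and 1188 genes in the other splits, against 7070, 10489 and 6289. The lists called by camera numbered 14, 17 and 15, with 9 in the highest other split of each pair.

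Mitotic genes fell with TGF-β1 (median -0.92) and again after EGF (median -0.79). Scaling between arrays is argued against, since the median after EGF nearest to 0 over the 3 other scalings was -0.69. The inhibitors Cdkn1a and Cdkn2b, raised in TGF-β1 cells, fell after EGF (smaller change -0.64). That they hold the genes down stays open, as their levels against control were not weighed. Time in culture, density or passage stays open too, since each treatment has 1 culture time, and so does the treatment itself, which the design names.

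Fos and Egr1 fell with TGF-β1 and rose after EGF, each with 3 identical values in control, where their spread is thus not known. Scaling is argued against, since their smallest change in either step over the 3 other scalings was 1.94. Loss and return of EGF signalling through ERK is a candidate. Of 11 ETS factor and feedback genes, 4 rose and 1 fell with TGF-β1 (median 0.093), counter to a loss. After EGF 3 rose and 5 fell (median -0.067, but 0.039, 0.030 and 0.026 under other scalings). Members going both ways leave the candidate open. The time from the last medium change to harvest also stays open, since 0 columns of the labels give it.

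Col1a1, Fn1 and Vim stood high in control cells and did not rise by more than 0.098 with TGF-β1. A ceiling of the signal is argued against for Vim, which changed by -0.48 and came back. For Col1a1 and Fn1 a ceiling stays open: of 15 other genes near the level of Col1a1, 7 rose (largest 0.28, Thbs1) and 4 fell (largest -0.60, Anxa2). Mesenchymal cells of another type may contribute. In control cells 2 of 12 stellate markers lay above the 75th percentile (Des 9.97, Ecm1 9.78). This decides nothing: 6656 of 18041 genes passed a filter at this level. Above it lay 16 of 21 mesenchymal markers, which this culture may express itself. Of progenitor and biliary genes 4 of 19 did, and of hepatocyte genes 2 of 23.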

How the results depend on the processing

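Of the alternatives, that without genes with 3 identical values in a group was chosen after seeing the data. Over all alternatives, named genes kept direction and side of the threshold in 7752 cases, lost the call in 266, gained one in 25 and reversed in 1. Lists did so in 1990, 177, 66 and 2, with fry among them, which asks another question. A stricter limit lowers counts by construction. Elsewhere the cause was not tested. Low signal over background limits dim genes most.

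Genes differing among the groups numbered 5000 with the 75th percentile filter and 5354 at an adjusted p of 0.01. After EGF these settings gave 4417 and 4774 genes, and EGF cells differed from controls in 2377 at an adjusted p of 0.01 and 8083 with array weights. Tested against a fold of 2, 211, 132 and 120 genes passed. With an estimated correlation camera called 0, 0 and 3 lists with TGF-β1, after EGF and between EGF cells and controls, with 8, 7 and 6 at an unadjusted p under 0.05, and fry, against no change, called 28 with TGF-β1 and 26 between EGF cells and controls. The lists after EGF numbered 10 with quantile normalization, 7 with either filter, 11 with array weights, 10 with the 6 compared arrays and 11 without genes with identical values.

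The share still different was 34.6% without a fold minimum. The remaining fraction was 0.324 with cyclic loess, 0.344 with median centring, 0.328 with quantile normalization, 0.317 with the 75th percentile filter, 0.218 without a fold minimum and 0.293 without genes with identical values. Fn1 turned to -0.083 with TGF-β1 under quantile normalization. After EGF camera reversed for cytokines with the 75th percentile filter (median 0.017). For genes induced by TGF-β (median 0.055) fry pointed down against no change, and camera, which did not call them, up against other genes.

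Leaving out 1 array gave 6671 to 8971 genes among the groups. With TGF-β1 it gave 4707 to 5943 genes, 363 to 394 with a fold of at least 2 and 14 to 19 lists. After EGF it gave 5864 to 9034 genes, 276 to 291 and 10 to 16 lists, and between EGF cells and controls 2954 to 4381, 217 to 223 and 14 to 15 lists. The share called back was 85.4% to 87.5%, that still different 66.8% to 72.4% and the remaining fraction 0.326 to 0.342. With a block for the replicate number 7095 genes differed, and 5044, 7137 and 3330 in the comparisons. Arrays of the same number correlated between -0.40 and 0.351 after group means were removed, so the numbers do not pair.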

Other observations

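Of 8 further lists, those of stress response and hepatocyte genes were called in at least 1 comparison, calls that ended with an estimated correlation and under other scalings, and the other 6 were not called by camera in the deposited values of all 9 arrays and all genes. Stress response genes gave 12 rises and 6 falls among 23 measured, 13 and 7 adjusted over the list alone (camera adjusted p = 0.00647, adjusted p = 0.417 with an estimated correlation) after EGF, with rises of the chaperone Hspa5 (0.69 ± 0.045) and Creld2 (0.62 ± 0.033) and falls of Phgdh (-0.50 ± 0.042) and Shmt2 (-0.44 ± 0.047). The stress response list lost its call under cyclic loess (adjusted p = 0.265), quantile normalization (0.123), the median filter (0.0626) and the 75th percentile filter (0.538), range 0.0038 to 0.538 over camera alternatives. For these genes EGF cells against controls gave 9 rises and 4 falls among 23 measured, 12 and 4 adjusted over the list alone (camera adjusted p = 0.00945, adjusted p = 0.439 with an estimated correlation). The stress response list lost its call under cyclic loess (adjusted p = 0.112), median centring (0.0541), quantile normalization (0.0766), the median filter (0.0981) and the 75th percentile filter (0.611), range 0.00335 to 0.611 over camera alternatives. With TGF-β1 the same list gave 5 rises and 7 falls among 23, 5 and 7 adjusted over the list alone (camera adjusted p = 0.13). Hepatocyte genes gave 1 rise and 10 falls among 23 measured, 1 and 10 adjusted over the list alone (camera adjusted p = 0.0462, adjusted p = 0.674 with an estimated correlation) after EGF, with a rise of Cebpa (1.16 ± 0.039) and falls of Fgg (-2.24 ± 0.15) and Arg1 (-0.88 ± 0.053). Hepatocyte genes lost their call on leaving out control array 2 (adjusted p = 0.0516), control array 3 (0.0569), TGF-β1 array 1 (0.088) and EGF array 1 (0.102) and under cyclic loess (0.269), median centring (0.0594), quantile normalization (0.372), the median filter (0.396), the 75th percentile filter (0.502), array weights (0.0636), removal of identical values (0.118) and the 6 compared arrays (0.0591), range 0.0278 to 0.674 over camera alternatives. They gave 3 rises and 1 fall among 23, 3 and 1 adjusted over the list alone (camera adjusted p = 0.349) with TGF-β1, and in EGF cells against controls 1 rose and 2 fell of 23, 1 and 2 adjusted over the list alone (camera adjusted p = 0.134). Hepatic progenitor and biliary genes gave 2 rises and 4 falls among 19, 2 and 4 adjusted over the list alone (camera adjusted p = 0.733) with TGF-β1, where the median (0.056) and the mean (-0.16) differed in sign and the test was downward. After EGF they gave 5 rises and 7 falls among 19, 5 and 8 adjusted over the list alone (camera adjusted p = 0.723), with a median of -0.10 against a mean of 0.15 and an upward test, which turned with median centring. Against controls they gave 3 rises and 5 falls among 19, 4 and 5 adjusted over the list alone (camera adjusted p = 0.704). Spp1 (2.65 ± 0.048) and Tspan8 (2.19 ± 0.066) rose after EGF, and Lgr5 (0.51 ± 0.050) rose with TGF-β1.

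The EGF receptor family and its ligands gave 6 rises and 2 falls among 16, 6 and 2 adjusted over the list alone (camera adjusted p = 0.0795) with TGF-β1. The EGF receptor list was called higher under the median filter (adjusted p = 0.0217), range 0.0217 to 0.247 over camera alternatives, the highest with an estimated correlation. This family gave 3 rises and 7 falls among 16, 4 and 7 adjusted over the list alone (camera adjusted p = 0.723) after EGF. Its median after EGF (-0.069) turned positive under the 3 other scalings. It gave 5 rises and 1 fall among 16, 5 and 1 adjusted over the list alone (camera adjusted p = 0.23) against controls. Against controls the negative median (-0.017), positive under the 3 other scalings, stood against a mean of 0.11 and an upward test. Hbegf, a ligand of the EGF receptor, changed by 1.00 ± 0.062 and then -1.04 ± 0.062, and Areg by -0.30 ± 0.056 and then 0.26 ± 0.056. Matrix proteases and their inhibitors gave 6 rises and 9 falls among 26, 6 and 9 adjusted over the list alone (camera adjusted p = 0.584) with TGF-β1. After EGF they gave 8 rises and 10 falls among 26, 8 and 11 adjusted over the list alone (camera adjusted p = 0.695), in a direction that turned with cyclic loess. Between EGF cells and controls they gave 5 rises and 6 falls among 26, 5 and 7 adjusted over the list alone (camera adjusted p = 0.412). The rises included Mmp2 (1.56 ± 0.051), and the falls Serpine2 (-0.95 ± 0.090). The median of that difference (-0.055) turned positive with median centring. For proteases the median (0.042) and mean (-0.10) differed in sign with TGF-β1, with a downward test, and likewise after EGF (-0.084 and 0.050), with an upward test and a median that turned with median centring and quantile normalization. Glycolysis and hypoxia genes gave 8 rises and 7 falls among 27, 9 and 8 adjusted over the list alone (camera adjusted p = 0.864) with TGF-β1, in a direction that turned with cyclic loess and quantile normalization and with a median (-0.016) and a downward test against the sign of the mean (0.025). These genes gave 11 rises and 8 falls among 27, 11 and 8 adjusted over the list alone (camera adjusted p = 0.128) after EGF. They also gave 7 rises and 8 falls among 27, 7 and 8 adjusted over the list alone (camera adjusted p = 0.575) against controls, with a median of -0.053, positive with median centring, a mean of 0.069 and an upward test. Pluripotency and stem cell factors gave 0 rises and 4 falls among 13, 0 and 4 adjusted over the list alone (camera adjusted p = 0.0966) with TGF-β1. The pluripotency list was called lower on leaving out control array 1 (adjusted p = 0.05) and under the median filter (0.0482), range 0.0482 to 0.346 over camera alternatives, the highest with an estimated correlation. In this group, the step after EGF gave 4 rises and 1 fall among 13, 4 and 1 adjusted over the list alone (camera adjusted p = 0.723), with a median of -0.087, positive with median centring, a mean of 0.0055 and an upward test. Against controls this group gave 0 rises and 2 falls among 13, 0 and 2 adjusted over the list alone (camera adjusted p = 0.154). Reference genes, often used as constant, gave 3 rises and 2 falls among 12, 4 and 3 adjusted over the list alone (camera adjusted p = 0.799) with TGF-β1. Against controls the reference genes gave 1 rise and 4 falls among 12, 2 and 4 adjusted over the list alone (camera adjusted p = 0.575). After EGF the reference genes gave 2 rises and 3 falls among 12, 2 and 3 adjusted over the list alone (camera adjusted p = 0.805). The direction of this list turned with cyclic loess and quantile normalization with TGF-β1 and with median centring after EGF. With TGF-β1 its median (-0.035) and test were negative against a mean of 0.050, and its median against controls (-0.022) turned positive with median centring. Hprt1 rose 2.09-fold with TGF-β1 (1.06 ± 0.074) and changed by -0.90 ± 0.074 after EGF, directions kept under each scaling.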
